A study of Homo sapiens with 9 samples.

How the data were processed

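RNA sequencing of human liver cancer cell lines was analysed from the table of counts per gene. The table covers 9 libraries, made from Hep3B, Huh7 and SNU449 cells left untreated or given THZ531 at 250 or 500 nM, with 1 library for each cell line and dose. THZ531 is a covalent inhibitor of CDK12 and CDK13, the kinases that pair with cyclin K and phosphorylate RNA polymerase II during transcription. Per the labels, polyadenylated RNA was made into stranded libraries with the TruSeq RNA kit. The submitters' processing notes name HISAT2 and HTSeq and the human genome build GRCh38. Versions of these tools, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited values are raw counts per Ensembl gene, which were whole numbers with column sums that differ between libraries, and no normalization by the authors was found in them. The labels disagree on the length of treatment. The sample characteristics give 48 h for all treated libraries, whereas the protocol gives 24 h for Hep3B and Huh7 and 48 h for SNU449.

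The total count per library ran from 5701981 to 20657610, which sets the precision of each value. Of 32990 genes in the table, 15479 passed filterByExpr on the dose groups and were tested. Counts were scaled with TMM factors and fitted in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood test, two-sided, and Benjamini-Hochberg adjustment over all tested genes at 0.05. The dose fit held a term for cell line and a term for each dose, so each dose was compared with the control of the same line, and it left 4 residual degrees of freedom. The replicates of a dose are therefore the 3 lines, and the spread is that of the response between lines, pooled over both doses. It also holds the smaller difference between the 250 and 500 nM libraries of a line. The 2 doses of a line thus act in part as replicates of each other. A fit on only the 6 libraries of a comparison does without this pooling. Its contrasts were 500 nM against control, 250 nM against control, 500 nM against 250 nM, and the mean of both doses against control. The fitted fold change of this additive model is not the mean of the 3 within-line ratios. The line fit held a mean and a treated term per line, with the 250 and 500 nM libraries as the 2 treated libraries of a line, and left 3 residual degrees of freedom. In the line fit a true difference between doses counts as spread. It gave an F test that the 3 responses are equal, the 3 pairwise differences, and, added after the data had been seen, the response within each line. No label says that the libraries of a line came from separately grown cultures, so the p-values measure the spread between these libraries only. Standard errors are the fold change divided by the root of the F statistic.

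For each treated library the log2 ratio to the control of its line was computed from TMM-scaled counts scaled to library size (CPM) with a prior count of 2. These within-line ratios have no replicate and no test. A ratio against 0 counts is given as a bound with a floor of 3 counts per library, and ratios with few counts are given with 95% intervals from the exact binomial (Clopper-Pearson) method. Shares of counts have 95% intervals by the same method. Intervals and floors cover counting error only.

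The comparisons, the 32 gene lists and the rule for naming genes were fixed before the data were examined. Named genes were CDK12, CDK13 and CCNK, and, for 500 nM against control, the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 CPM of at least 3 and the same direction in all treated libraries. The 250 nM comparison and 500 against 250 nM took the 5 largest each way by the same rule, and if fewer than 5 passed, the largest changes were named as not past the test. Each list gave up to 4 members with the smallest p, or up to 10 for the homologous recombination and checkpoint lists. The line difference gave the 5 genes with the smallest p of the F test and the 3 smallest for each pair of lines. Within each line, the 5 largest ratios each way at 500 nM were taken among genes with at least 100 counts in 1 library and the same direction at both doses. The text names part of the genes these rules chose. Other genes named in the text were chosen after their values were seen. Of the 644 list entries 641 were found in the table. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 with Benjamini-Hochberg adjustment over the lists, again with an estimated correlation, and with fry.

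Gene lengths were taken from the start and end positions in the table. Exonic length, exon number and GC content came from the GENCODE v29 annotation, in which 32344 genes (98.04%) were found by Ensembl identifier, 99.99% of them at the same place. Of the tested genes 99.2% had an exonic length and 99.1% a GC content. Relations with length are rank correlations across genes, which are not independent replicates.

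Alternatives tried were DESeq2 size factors inside edgeR, total-count scaling, no filter on low counts, a stricter filter of at least 5 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, each line left out in turn, no term for cell line, a fit on the 6 libraries of a comparison, other prior counts, and other measures of length. A fit on each line's 3 libraries alone and a fit without the Huh7 500 nM library, which has the lowest total, were added after the data had been seen. The fits were tested on simulated counts with known changes in 200 genes. For 500 nM against control they recovered 17.9% of simulated 2-fold, 88.1% of 4-fold and 92.4% of 8-fold changes, with 18 unchanged genes called. These changes were set alike in all 3 lines, so the shares recovered do not hold for changes that 1 line lacks. For the line difference, simulated as changes in Hep3B and Huh7 only, the shares recovered were 1.49%, 46.3% and 75.8%. Here 15 unchanged genes were called beside 1, 31 and 50 recovered. Within Hep3B, Huh7 and SNU449 23, 11 and 12 unchanged genes were called. Adjusted p-values may therefore be too low in part of the comparisons. Annotation tables and figures were made with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Transcripts that mark sex were left out of the text and figures. Genes were not filtered by chromosome in the fits or the naming rules, so named genes include X-linked ones.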

Results

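The series measured poly(A) RNA in 3 human liver cancer cell lines to describe the effect of THZ531 on gene expression. Hep3B and Huh7 are hepatocyte-like lines, and SNU449 is a mesenchymal-like line with little hepatocyte RNA. Each line gave 1 control library, 1 library at 250 nM and 1 at 500 nM, so each dose has n = 3 lines and no replicate within a line. Total counts for control, 250 and 500 nM were 20657610, 13325709 and 11582266 in Hep3B. They were 14423043, 8557515 and 5701981 in Huh7, and 14023600, 12875070 and 15553604 in SNU449. The share of counts from mitochondrial genes was 4.28% (95% interval 4.27 to 4.28) in the Hep3B control, 10.6% (10.6 to 10.6) at 250 nM and 12.4% (12.4 to 12.4) at 500 nM. In Huh7 it was 3.85% (3.84 to 3.86), 8.14% (8.13 to 8.16) and 13.1% (13.05 to 13.10). In SNU449 it was 4.32% (4.31 to 4.33), 4.34% (4.33 to 4.35) and 4.47% (4.46 to 4.48). Across genes, the SNU449 control correlated with its own treated libraries at r = 0.995 and 0.994 on the log2 scale. The same correlations were 0.929 and 0.917 in Hep3B and 0.936 and 0.868 in Huh7.

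**Figure D1:**
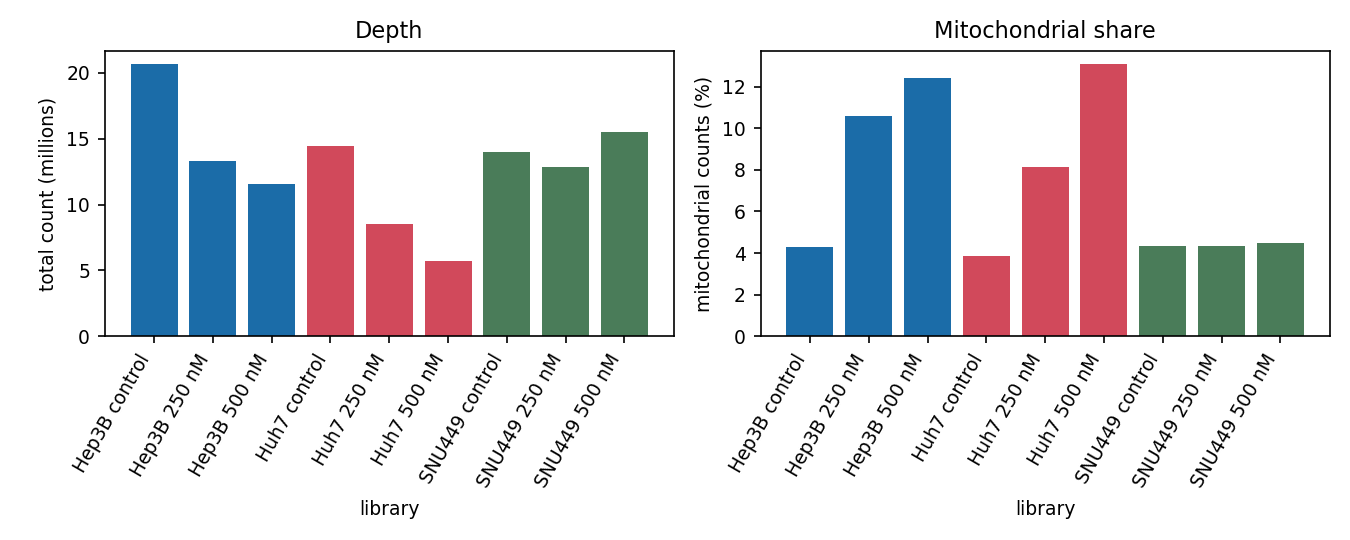
Bars show the total count (left) and the percent of counts from mitochondrial genes (right) for each of the 9 libraries. The mitochondrial share reached 12.4% in Hep3B and 13.1% in Huh7 at 500 nM and was 4.47% in SNU449.

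The first comparison asked which genes changed at 500 nM THZ531 across the lines. FOS, the AP-1 transcription factor of the immediate early response, rose most among the named genes, with a log2 fold change of 7.95 ± 0.76 (SE, n = 3 lines, adjusted p = 0.000351). The histone gene HIST2H2BE rose by 4.90 ± 0.93 (adjusted p = 0.0117). A1CF, the cofactor of APOB mRNA editing, fell by 2.67 ± 0.33 (adjusted p = 0.00100), and ATP10D, a phospholipid flippase, fell by 2.22 ± 0.44 (adjusted p = 0.0138). By the rule itself, each gene chosen by size of change at this dose had the same direction in 6 of 6 treated libraries. A1CF in SNU449 rested on at most 1 count per library. Most of the size came from Hep3B and Huh7. The FOS log2 ratios were 7.92 in Hep3B, 8.18 in Huh7 and 1.74 in SNU449, where the control held 3 counts and the 500 nM library 17.

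In all, 646 of 15479 genes passed at 500 nM, 534 higher and 112 lower. The median log2 ratio of the 534 higher genes was 3.11 in Hep3B, 3.85 in Huh7 and 0.32 in SNU449 at 500 nM. Of these genes 524 were at least 2-fold higher in Hep3B, 533 in Huh7 and 52 in SNU449. The 112 lower genes had medians of -1.97, -1.97 and -0.25 in the same order. The other named genes that rose were VGF, a secreted neuropeptide precursor (7.47 ± 1.59, adjusted p = 0.0203), MIR663AHG, a microRNA host transcript (5.91 ± 1.16), and FOSB, a further AP-1 member (4.57 ± 0.77). DLX2, a homeobox factor, rose by 4.48 ± 0.96. VGF had 0 counts in the Hep3B control, so its fitted size depends on the prior and is not a bound. Unclassified or noncoding genes among them were CTB-129P6.7 (5.73 ± 0.41, adjusted p = 3.16e-05), RP13-516M14.1 (4.23 ± 0.80) and CTD-2371O3.3 (4.07 ± 0.77). CTB-129P6.7 overlaps APOC1 and APOE, FOSB overlaps ERCC1, and CTD-2371O3.3 is antisense to ZNF143, so position alone does not assign reads there. The other named falls were KRCC1, CHST9, SPTLC3, MAVS, PPP3CB, LIN7A, TMEM37 and GK, from -2.14 to -1.75, with the largest adjusted p = 0.0457. MAVS is the mitochondrial adaptor of RNA sensing, SPTLC3 a subunit of serine palmitoyltransferase and PPP3CB a catalytic subunit of calcineurin. On GRCh38, FOS (ENSG00000170345) lies on chromosome 14 from 75278774 to 75282230 and CTB-129P6.7 (ENSG00000280087) on chromosome 19 from 44909375 to 44914968. A1CF (ENSG00000148584) lies on chromosome 10 from 50799409 to 50885675. ATP10D (ENSG00000145246) lies on chromosome 4 from 47485288 to 47593486. The targets of the compound did not pass: CDK12 had 0.583 as its adjusted p (log2 fold change -0.24 ± 0.27, lower in 4 of 6 libraries), CDK13 -0.29 ± 0.24 and CCNK 0.24 ± 0.23.

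**Figure D2:**
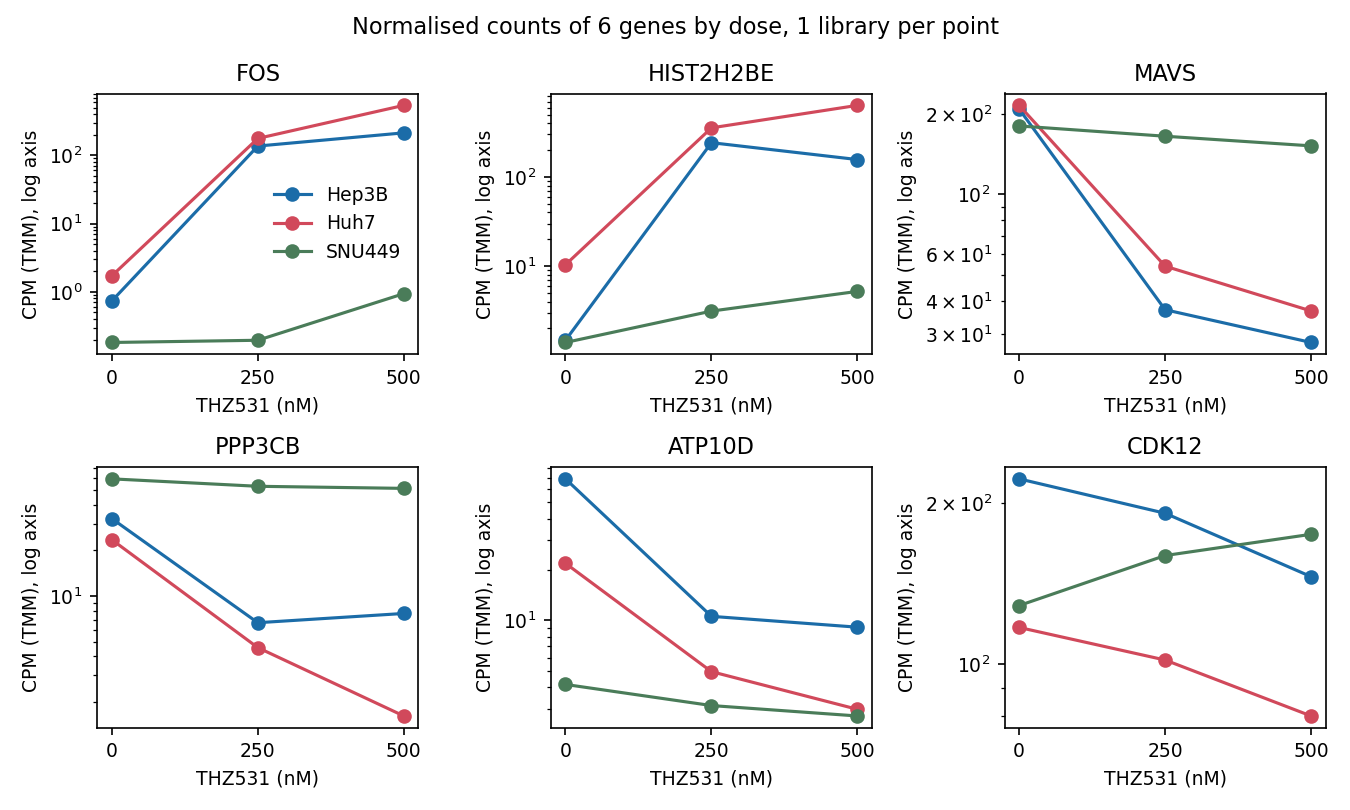
Points show the TMM-scaled CPM (log axis) of 6 genes at 0, 250 and 500 nM, 1 library per point, with lines joining the libraries of a cell line. FOS reached 213 CPM in Hep3B and 539 in Huh7 at 500 nM and in SNU449 stood at 0.181 in the control and 0.941 at 500 nM.

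Genes that are not protein-coding made up 304 of the 534 higher genes (56.9%), against 14.6% of all tested genes and 8.04% of the 112 lower genes. Antisense genes gave 113 of them out of 688 tested, and lincRNAs 90 out of 724. Processed pseudogenes gave 35 out of 176. The strand setting of the counting is not given, and these counts depend on it. At 500 nM noncoding genes that overlap a protein-coding gene had median log2 ratios of 0.96 in Hep3B and 1.42 in Huh7, against 0.46 and 0.63 for those that overlap none.

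Of the immediate early genes, the transcription factors and phosphatases first induced by stimuli, 11 of 19 rose at 500 nM over all genes, 16 adjusted over the list alone and none fell. Their median log2 fold change was 2.75 (camera adjusted p = 8.4e-12, adjusted p = 0.593 with an estimated correlation), while the library medians at 500 nM were 3.69 in Hep3B, 3.51 in Huh7 and 0.11 in SNU449. KLF10 was at 1.75 ± 0.38 (adjusted p = 0.0211, higher in 6 of 6 libraries) and ATF3 at 2.95 ± 0.68 (adjusted p = 0.0306, 6 of 6). Replication-dependent and linker histones had 10 of 15 genes higher, 12 adjusted over the list alone, and a median of 2.55 (camera adjusted p = 2.4e-10, adjusted p = 0.593 with an estimated correlation). HIST1H1C, a linker histone, was at 2.14 ± 0.45 (adjusted p = 0.0197, 6 of 6). Since the libraries hold polyadenylated RNA, histone values here and elsewhere cover polyadenylated transcripts only and do not measure total histone RNA. Hepatocyte products, the secreted liver proteins, had 4 of 20 higher (VTN, TTR, APOA1 and APOA2), 11 adjusted over the list alone and a median of 1.22 (camera adjusted p = 0.000193, adjusted p = 0.593 with an estimated correlation). TTR, the thyroxine carrier, rose by 1.65 ± 0.36 (adjusted p = 0.0229, 5 of 6), although each of these 4 genes had 4 or fewer counts in every SNU449 library. NF-kB targets had 4 of 14 higher (CXCL2, CCL20, TNF and CXCL8), 6 adjusted over the list alone, and a camera adjusted p = 0.00713 (adjusted p = 0.593 with an estimated correlation). Their median was 0.34, and 0.03 under total-count scaling. The chemokine CXCL2 rose by 3.87 ± 0.71 (adjusted p = 0.0104, 6 of 6). Mesenchymal and TGF-beta genes had 2 of 18 higher, SNAI2 among them, 7 adjusted over the list alone, and a median of 0.92 (camera adjusted p = 5.4e-05, adjusted p = 0.593 with an estimated correlation). Fry called none of the 13 lists that camera called at 500 nM.

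The protein synthesis and respiration lists passed camera at 500 nM although no member passed alone over all genes. Ribosomal protein genes had a median of 0.88 over 75 genes, 34 of them higher adjusted over the list alone (camera adjusted p = 4.4e-15, adjusted p = 0.593 with an estimated correlation). The 13 mitochondrially encoded genes had a median of 1.35, with all 13 higher adjusted over the list alone (camera adjusted p = 5.3e-07, adjusted p = 0.593 with an estimated correlation). The rise in mitochondrial share of counts ran in the same libraries. Nuclear oxidative phosphorylation genes had 0 of 30 past the threshold, 8 adjusted over the list alone, and a median of 0.54 (camera adjusted p = 0.000226, adjusted p = 0.593 with an estimated correlation). Under total-count scaling that median was 0.02, and it turned to -0.03 for both doses averaged and to -0.16 within Huh7. Housekeeping genes, often used as stable references, had 0 of 10 past the threshold, 6 higher and 1 lower adjusted over the list alone, and a median of 1.08 (camera adjusted p = 0.0495, adjusted p = 0.593 with an estimated correlation). The unfolded protein list had 1 of 17 higher, PPP1R15A, the phosphatase subunit that reverses the stress block of translation (1.60 ± 0.38, adjusted p = 0.0329, 6 of 6), 5 adjusted over the list alone, and a camera adjusted p = 0.0495 (adjusted p = 0.593 with an estimated correlation). The median of this list was 0.54, and 0.02 under total-count scaling. The member with the smallest p was RPS29, of the small ribosomal subunit, among ribosomal protein genes (1.35 ± 0.38, adjusted p = 0.0618, higher in 4 of 6 libraries), and MT-ND3, of respiratory complex I, among mitochondrially encoded genes (1.52 ± 0.43, adjusted p = 0.0613, 6 of 6).

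Homologous recombination and Fanconi anaemia genes, which repair double-strand breaks and crosslinks, lay lower as a list: 0 of 31 passed either over all genes or adjusted over the list alone, and the median was -0.42 (camera adjusted p = 0.000226, adjusted p = 0.593 with an estimated correlation). BRCA1 stood at -1.29 ± 0.36 (adjusted p = 0.0570), RAD52 at -1.25 ± 0.37 and XRCC2 at -1.25 ± 0.38, none past the threshold. The DNA damage checkpoint list had 1 of 19 lower (1 also adjusted over the list alone), the apical kinase ATR, which fell by 1.37 ± 0.34 (adjusted p = 0.0398, lower in 6 of 6 libraries). Its camera adjusted p = 0.0247, and adjusted p = 0.593 with an estimated correlation. Hepatocyte transcription factors had 1 of 13 lower and a median of -0.85. Adjusted over the list alone 3 were higher and 7 lower, with a camera adjusted p = 0.0495 and adjusted p = 0.593 with an estimated correlation.

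The other 19 lists did not pass camera at 500 nM (adjusted p from 0.0658 to 0.847). Their medians lay between -0.31 and 1.08, and those of the p53 (0.14), cholesterol (0.11), heat shock (0.18), xenobiotic (0.28), interferon (0.04), hypoxia (0.46) and splicing (0.14) lists turn below 0 under total-count scaling. Single genes rose in 9 of the lists with 1 call each: CDK11A among transcriptional kinases, GADD45A among p53 targets, BCL2A1 among apoptosis regulators, CYP1A1 in the xenobiotic list, ISG15 among interferon genes, ADM in the hypoxia list, PCF11 among cleavage factors, LYZ among immune markers and LUM among fibroblast markers. CDK11A has a near-identical copy, CDK11B. CYP1A1, the aryl hydrocarbon receptor target, rose by 1.85 ± 0.32 (adjusted p = 0.00674, 6 of 6 libraries), and PCF11, a transcription termination factor, by 1.49 ± 0.37 (adjusted p = 0.0385, 6 of 6). In the epithelial list KRT19, CLDN4 and EPCAM rose, 3 of 13, and in the receptor kinase list ERBB3 fell (-1.43 ± 0.32, adjusted p = 0.0254, 6 of 6), 1 of 24. Adjusted over the list alone, higher and lower genes numbered 5 and 1 of 16 transcriptional kinases, 3 and 2 of 19 p53 targets, 1 and 0 of 19 apoptosis regulators, 1 and 0 of 12 xenobiotic genes, and 1 and 0 of 14 interferon genes. They numbered 5 and 2 of 13 epithelial genes, 1 and 1 of 16 hypoxia genes, 0 and 1 of 24 receptor kinases, 3 and 3 of 17 cleavage factors, 2 and 0 of 4 immune markers, and 1 and 0 of 5 fibroblast markers. In the 8 lists where 0 genes passed in edgeR, those adjusted over the list alone were 3 lower of 38 DNA replication genes and 3 higher of 12 heat shock genes. They were 0 of 3 inhibitor targets, 0 of 29 excision and end-joining repair genes, 0 of 23 mitosis genes, 0 of 20 cholesterol genes, 0 of 9 Wnt targets and 0 of 23 splicing factors.

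Total-count scaling, in place of TMM, shifted the median log2 ratio of all genes by -0.39 and -0.55 in Hep3B, -0.48 and -0.88 in Huh7, and by 0.00 and -0.01 in SNU449 at 250 and 500 nM. Changes are therefore given relative to the bulk of genes; under total counts 2706 genes passed at 500 nM, 709 higher and 1997 lower. The count rests on single lines: it was 4 without Hep3B, 14 without Huh7, 6324 without SNU449 and 30 without the Huh7 500 nM library, and DESeq2 gave 1556. On only the 6 libraries of this comparison, without the spread pooled over doses, it was 76.

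**Figure D3:**
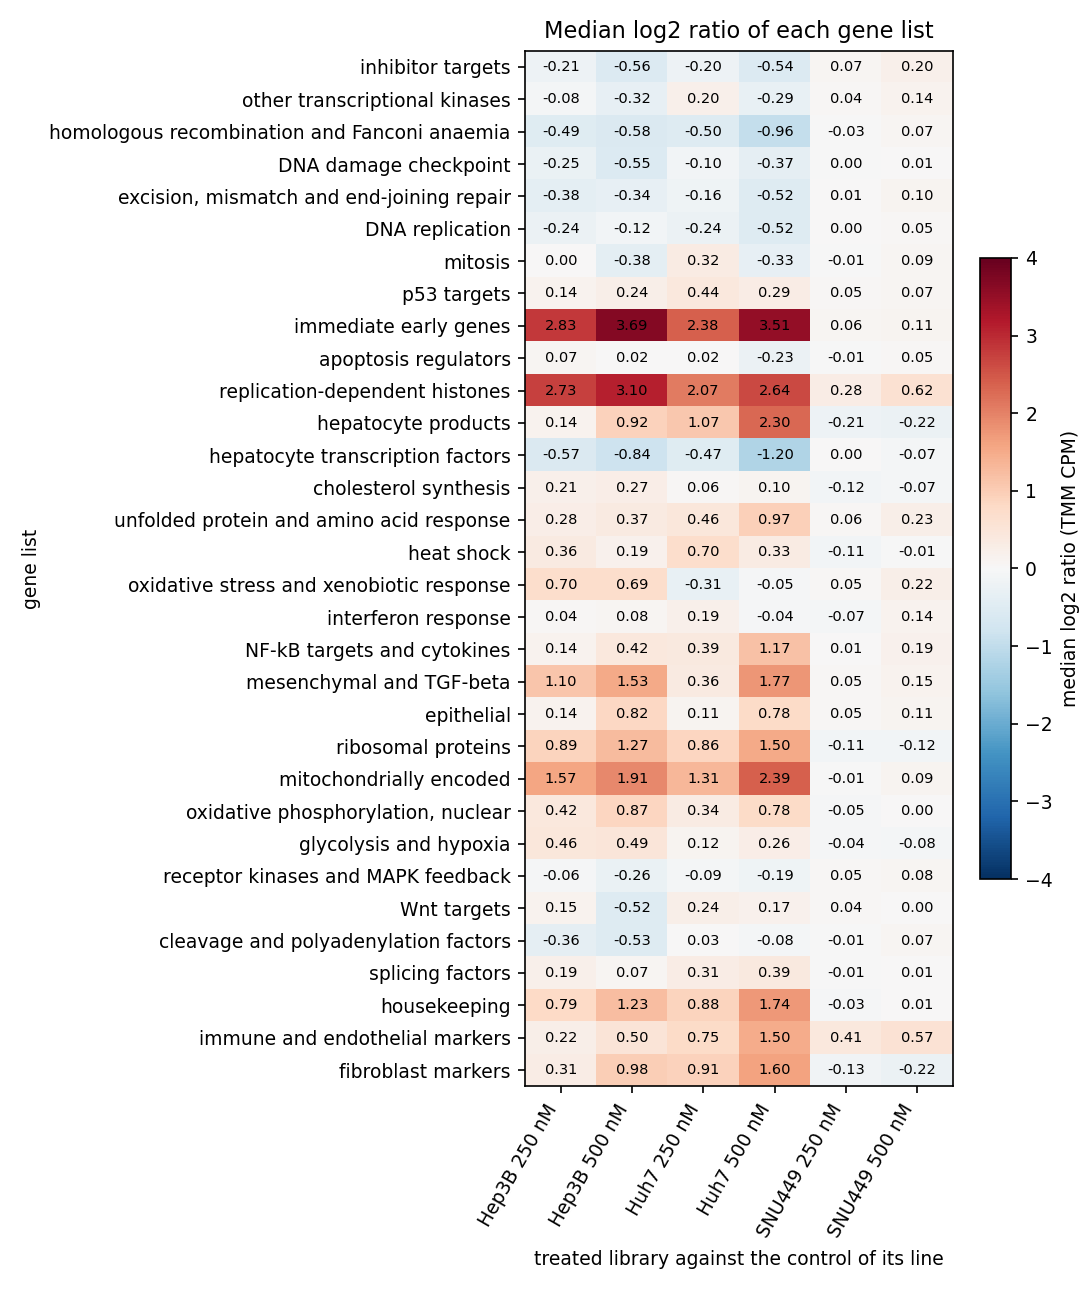
Colours and numbers show the median log2 ratio (TMM CPM) of each of the 32 lists in each treated library against the control of its line. Immediate early genes stood at 3.69 in Hep3B and 3.51 in Huh7 at 500 nM and at 0.11 in SNU449; under total-count scaling the medians of 18 lists, among them the p53, apoptosis, cholesterol, heat shock, interferon, splicing, NF-kB, unfolded protein and oxidative phosphorylation lists, turn from above to below 0 in 1 or more Hep3B or Huh7 libraries.

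At 250 nM FOS rose by 6.75 ± 0.73 (adjusted p = 0.000865, higher in 6 of 6 libraries) and HIST2H2BE by 4.75 ± 0.95 (adjusted p = 0.0308). CTB-129P6.7 rose by 5.50 ± 0.41 (adjusted p = 5.2e-05) and RP13-516M14.1 by 3.78 ± 0.79. The largest named falls were RASL10B, a small GTPase (-2.43 ± 0.39, adjusted p = 0.0114), A1CF (-2.22 ± 0.32), ATP10D (-1.91 ± 0.42), ABCC6, a hepatic transporter (-1.88 ± 0.39), and the adhesion gene MPZL2 (-1.69 ± 0.29). Immediate early genes had 3 of 19 higher (9 adjusted over the list alone, median 1.76) and histones 4 of 15 (10 adjusted over the list alone, median 1.89). Camera also called mesenchymal (median 0.42), ribosomal (0.50) and mitochondrially encoded genes (0.86) higher and homologous recombination genes lower (median -0.28, camera adjusted p = 0.00208). For all 6 of these lists adjusted p = 0.707 with an estimated correlation, and fry called none. At this dose 188 genes passed, 164 higher and 24 lower, or 268 higher and 99 lower under total counts. Of the 164 higher genes 162 were also among the 534 of the higher dose, where independent draws give 5.66. Simulations with no treatment effect at either dose gave a mean of 0.10. They cannot show how much shared controls add when many genes respond. Of the 24 lower genes 15 were shared with the 112, against 0.174 for independent draws. Both doses use the same 3 controls, which cannot be split, so part of the excess may come from these controls. The count was 0 without Hep3B, 15 without Huh7, 3910 without SNU449, and 92 without the Huh7 500 nM library. On only the 6 libraries of this comparison it was 1.

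The comparison of 500 with 250 nM asked for a dose effect and found 0 genes past the threshold in edgeR, with 339 at an unadjusted p under 0.05. DESeq2 and limma-voom also gave 0. The highest values named by the rule, none past the threshold (smallest adjusted p = 0.968), were the chemokine CXCL2 at 2.51, the AP-1 gene JUNB at 1.86, MIR663AHG at 1.501, GEM, a small GTPase, at 1.48, and GADD45A, a stress sensor, at 1.34. The lowest were NFATC2 and TOX3 at -0.72, BCORL1 at -0.71, SGK2 at -0.62 and TET1 at -0.59. JUNB stood at 31.3, 224 and 830 CPM in Hep3B, at 19.5, 198 and 1077 CPM in Huh7, and at 27.6, 32.3 and 29.8 CPM in SNU449. A fit on the 6 treated libraries alone called 44 genes, all higher at 500 nM, and the fit without SNU449 called 5.

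Averaged over both doses, FOS (7.35 ± 0.73, adjusted p = 0.000422) and HIST2H2BE (4.83 ± 0.90, adjusted p = 0.0113) were higher. The editing cofactor A1CF fell by 2.44 ± 0.25 (adjusted p = 0.000431). The same direction in all 6 treated libraries was part of the rule that named these genes. Both doses together gave 801 genes, 535 higher and 266 lower. Under total counts 784 were higher and 2511 lower. The count was 3 without Hep3B, 26 without Huh7, 6290 without SNU449, and 131 without the Huh7 500 nM library.

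The response within each line was then compared, with both treated libraries of a line against its control. Each of these tests, in Hep3B and Huh7 as in SNU449, rests on 1 control library. A deviation of that control enters both ratios of the line and is not part of the standard error or p. In Hep3B and Huh7 most immediate early genes, histones and mitochondrial transcripts rose, part of the ribosomal protein genes rose, and some genes of homologous recombination fell. In SNU449 no gene passed. FOS rose by 7.88 ± 0.95 in Hep3B (adjusted p = 0.00147) and 7.69 ± 0.92 in Huh7 (adjusted p = 0.00150), higher in both treated libraries of each line. BRCA1, the tumour suppressor of homologous recombination, fell by 1.42 ± 0.29 in Hep3B (adjusted p = 0.00900) and by 2.11 ± 0.31 in Huh7 (adjusted p = 0.00238), lower in both libraries of each. Immediate early genes passed for 16 of 19 in Hep3B and 17 in Huh7, histones for 13 and 10 of 15, ribosomal proteins for 20 and 36 of 75, and mitochondrially encoded genes for 10 and 12 of 13. Homologous recombination genes fell for 6 and 9 of 31, among them BRCA2, RAD52 and XRCC2 in both lines. Hepatocyte products rose for 12 of 20 in Huh7, with ALB at 2.15 ± 0.52 (adjusted p = 0.0166, both libraries), whereas in Hep3B 0 rose past the threshold and 1 fell, APOB. The list median was 1.79 in Huh7 and 0.58 in Hep3B, where 13 of 20 stood higher at 250 nM and 18 at 500 nM. Under total counts the Hep3B library medians were -0.28 at 250 nM and 0.33 at 500 nM. No single product passed the test of a difference between these lines. Camera gave adjusted p = 0.596 in Hep3B and 0.681 in Huh7 with an estimated correlation for the lists of immediate early genes, histones, ribosomal, mitochondrial and homologous recombination genes.

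Hep3B had 2560 genes past the threshold, 1520 higher and 1040 lower, and Huh7 2994, 2059 higher and 935 lower. Under total counts the split was 1082 and 2405 in Hep3B and 1212 and 3562 in Huh7. Of the higher genes 1112 were shared by both lines (202 for independent draws), and of the lower genes 404 (62.8 for independent draws), while 8 moved in opposite ways. Across genes, the log2 ratios of Hep3B and Huh7 libraries correlated at r = 0.67 to 0.77, and those of either with SNU449 at 0.02 to 0.10. SNU449 had 0 genes in edgeR, with 68 at an unadjusted p under 0.05, and 0 in DESeq2 and limma-voom. A fit on its own 3 libraries, added after the data had been seen, called 186, and it rests on 1 control library. In simulated counts the line fit recovered 13.4% of 2-fold and 68.7% of 4-fold changes within SNU449, so its 0 calls leave smaller changes open. A check that the compound acted in SNU449 is not given in the sources used here. The median absolute log2 ratio at 500 nM was 0.676 in Hep3B, 0.857 in Huh7 and 0.143 in SNU449. In SNU449 the histone list passed camera (median 0.52, adjusted p = 1.5e-09) and the ribosomal list lay lower (median -0.11, adjusted p = 0.00355), with adjusted p = 0.960 with an estimated correlation for both. Fitted on its own 3 libraries, Huh7 had 1094 genes, 979 higher and 115 lower. The Hep3B count was 5170 without Huh7, 2126 without SNU449 and 5385 without the Huh7 500 nM library.

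As values without a test, Hep3B at 500 nM had FOS 290-fold higher (95% interval 183 to 491), VGF at least 248-fold and the keratin-associated gene KRTAP2-3 at least 215-fold higher by the floor of 3 counts (exact 95% lower limits 201 and 174, which also carry the error of the treated count), MIR663AHG 167-fold, and GEM 755-fold (134 to 29941, from 1 control count). Lower in Hep3B were the sodium channel gene SCN7A, at 357 raw counts in the control and 1 raw count at 500 nM, the transporter SLC16A6 (259 and 1), C19orf80 (2444 and 31), MPV17L (508 and 11) and the calcium pump ATP2B2 (1515 and 38). Raw counts overstate these falls, since the treated library is smaller. The scaled ratios to control were 0.00753 for SCN7A (0.000190 to 0.0422) and 0.0104 for SLC16A6 (0.000262 to 0.0583). They were 0.0341 for C19orf80, 0.0582 for MPV17L and 0.0674 for ATP2B2. In Huh7 at 500 nM VGF was 1210-fold (613 to 2807), AMH, the anti-Müllerian hormone gene, 814-fold (316 to 2995), FOS 314-fold, MIR663AHG 214-fold and MEX3B, an RNA-binding protein gene, 145-fold higher. Lower in Huh7 were FBXO10 (280 raw counts in the control and 3 at 500 nM), ATP2B2 (727 and 9), DNAJC18 (104 and 1), PPP3CB (426 and 6) and SSPN (140 and 2). Their scaled ratios to control were 0.0523 (0.0107 to 0.154), 0.0604 (0.0275 to 0.115), 0.0469 (0.00118 to 0.267), 0.0687 (0.0251 to 0.151) and 0.0697 (0.00836 to 0.257) in that order. In SNU449 the largest ratios were 4.17 for the pseudogene ATP5A1P6 (2.73 to 6.58), 2.90 for UNC13D, 2.43 for BAI3, 2.26 for FGGY and 2.19 for LAMB3, a laminin chain. The lowest were 0.258 for FER1L4, 0.446 for PPP2R3A, 0.451 for KIF12, 0.464 for SOD3 and 0.479 for CRYM. Genes at least 4-fold higher at both doses numbered 800 in Hep3B, 840 in Huh7 and 1 in SNU449, and those lower 102, 61 and 0. The total for SNU449 was 63 with a prior count of 0.5 and 0 with a prior count of 5.

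Whether the response itself differs between lines was tested next, again with 1 control library per line. AMH rose in Huh7 (9.18 ± 0.82) and Hep3B (6.24 ± 0.65) and stood at 0.21 in SNU449, and the F test gave adjusted p = 0.00761. TSC22D3, a glucocorticoid-induced leucine zipper gene, NMB, a bombesin-like peptide gene, ARRDC2 and RHBDL1 had adjusted p = 0.0192 each. ARRDC2, an arrestin-domain gene, was the 1 gene that differed between Huh7 and Hep3B, at 5.44 ± 0.66 (adjusted p = 0.0465, higher in both Huh7 libraries and lower in both of Hep3B). PLK2, a polo-like kinase, responded less in SNU449 than in Hep3B, with a difference of -5.19 ± 0.67 (adjusted p = 0.0279). S100A14 and CDKN1C did not pass between Huh7 and Hep3B (adjusted p = 0.0529 and 0.115, differences 5.46 ± 0.75 and 3.48 ± 0.53). The F test called 177 genes. The pairwise tests, which are separate and not subsets of it, called 53 between SNU449 and Hep3B (4 higher and 49 lower in SNU449) and 245 between SNU449 and Huh7 (7 and 238). Camera found the immediate early list lower in SNU449 than in Hep3B (median difference -3.46, adjusted p = 9.1e-13, adjusted p = 0.541 with an estimated correlation) and the homologous recombination list higher (0.56, adjusted p = 0.000364, adjusted p = 0.541 with an estimated correlation). Hepatocyte products lay higher in Huh7 than in Hep3B (1.14, adjusted p = 2.6e-05, adjusted p = 0.959 with an estimated correlation). The count of 177 was 0 without Hep3B, 1183 without Huh7, 17 without SNU449 and 842 without the Huh7 500 nM library. It was 1 with DESeq2 size factors.

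Because the compound's targets act during elongation, ratios were set against gene length. Genes under 5 kb stood higher and genes over 20 kb lower in Hep3B and Huh7. At 500 nM the 2356 genes under 5 kb had a median log2 ratio of 1.04 in Hep3B, 1.52 in Huh7 and -0.04 in SNU449. The 4189 genes of 50 to 200 kb had -0.33, -0.59 and 0.03. The 1086 genes over 200 kb had -0.15, -0.50 and 0.01, above the class before it in Hep3B and Huh7, whereas in Huh7 at 250 nM the median went from -0.18 to -0.24. Spearman's rho across 15479 genes was -0.272 and -0.318 in Hep3B, -0.303 and -0.439 in Huh7, and 0.005 and 0.078 in SNU449, at 250 and 500 nM. Genes are not independent replicates, so no p is given for these 6 relations. Under total counts rho was -0.271 and -0.316 in Hep3B and -0.308 and -0.442 in Huh7, while the medians of genes of 5 to 20 kb turned, in Huh7 at 500 nM from 0.38 to -0.49.

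**Figure D4:**
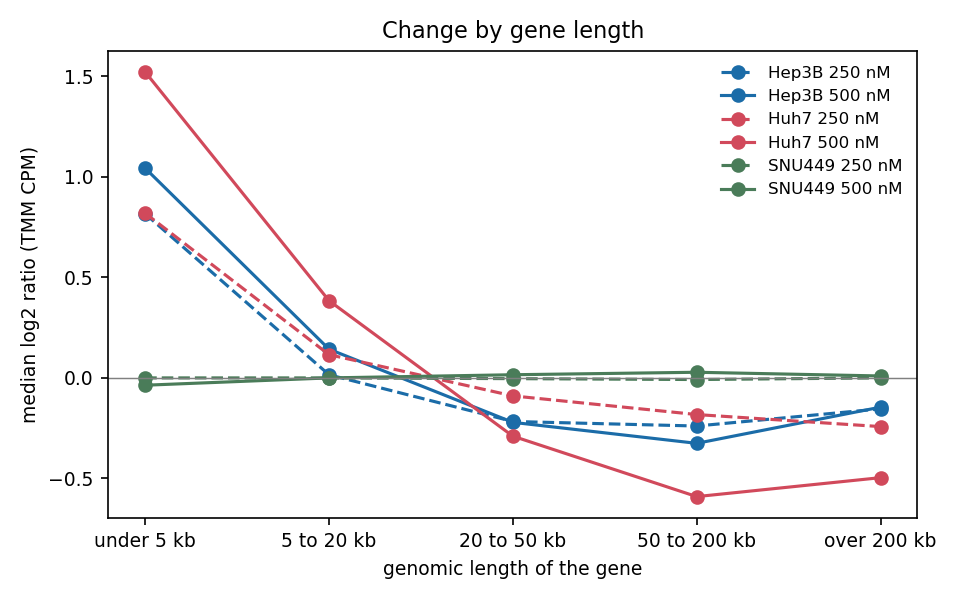
Points show the median log2 ratio (TMM CPM) of the genes in 5 classes of genomic length, for each treated library. Genes under 5 kb stood at 1.52 and genes of 50 to 200 kb at -0.59 in Huh7 at 500 nM, whereas the SNU449 medians lie close to 0; under total-count scaling the medians of genes of 5 to 20 kb turn from above to below 0 in all 4 Hep3B and Huh7 libraries.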

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

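Tests in this part chosen only after the result was seen were the depth and exposure-time checks of SNU449, the fit on its libraries alone, and the bootstrap interval for exonic length.

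The lines differed in response: 177 genes by the F test, 1 between Huh7 and Hep3B, 53 between SNU449 and Hep3B and 245 between SNU449 and Huh7. SNU449 might respond less because of shallow sequencing, a different or ineffective exposure, or its own biology. Its lowest treated total, 12875070 at 250 nM, lies above 8557515 and 11582266 of responding libraries but below 13325709 of Hep3B at 250 nM. At 500 nM SNU449, with 15553604, was deeper than every treated Hep3B and Huh7 library, which argues against depth. Its median absolute log2 ratio at 500 nM, 0.143 against 0.676 in Hep3B, uses no shared spread and argues against it as the cause of smaller ratios; its own fit, on 1 control, called 186 genes where the shared fit called 0 (6.29% of the number in Hep3B alone, with 1094 in Huh7 alone), so part of the missing calls stays open. Exposure time stays open, since 0 lines have treated libraries at both times. How far the compound acted in SNU449 was not tested and stays open too. There the histone list stood higher (median 0.52), but across all genes the log2 ratios correlated with those of Hep3B and Huh7 at only r = 0.02 to 0.10.

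By gene, the SNU449 response minus that of Hep3B, in log2, was -11.42 for VGF, -5.49 for HIST2H2BE, -8.55 for GEM, -7.08 for HIST1H2BG, -4.50 for TSC22D3, -5.19 for PLK2, -11.22 for KRTAP2-3 and 4.42 for MPV17L. SNU449 minus Huh7 was -6.14 for DLX2, -2.87 for HEXIM1, -2.85 for CDC20, -2.68 for COL3A1, -8.97 for AMH, -4.70 for NMB, -4.78 for RHBDL1, -3.66 for CDKN1C and -6.53 for MEX3B. Huh7 minus Hep3B was 5.44 for ARRDC2, 5.46 for S100A14 and 8.62 for SCN7A. The pairwise adjusted p was 0.0544 for KRTAP2-3, 0.0529 for S100A14 and 0.0525 for SCN7A, which passed the F test only, and sizes with 0 or 1 counts in a group are no bounds.

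Lists are given here only where camera at the preset correlation had an adjusted p under 0.05 for the difference. The differences quoted in the Results did not pass camera with an estimated correlation. By list, the median response of Huh7 minus Hep3B was -1.11 for histones, 1.14 for hepatocyte products and -1.05 for the xenobiotic list. SNU449 minus Hep3B was 0.56 for homologous recombination, -3.46 for immediate early genes, -2.64 for histones, -0.44 for heat shock, -0.87 for the xenobiotic list and -1.45 for mesenchymal genes. It was -1.24 for ribosomal proteins, -1.71 for mitochondrially encoded genes, -0.74 for nuclear oxidative phosphorylation and -0.95 for housekeeping genes. SNU449 minus Huh7 was 0.73 for homologous recombination, -2.87 for immediate early genes, -1.91 for histones, -1.90 for hepatocyte products, -0.59 for heat shock and -0.94 for mesenchymal genes. It was -1.38 for ribosomal proteins, -1.84 for mitochondrially encoded genes, -0.68 for nuclear oxidative phosphorylation, -1.41 for housekeeping genes and -1.54 for fibroblast markers. Under total-count scaling both heat shock differences and the oxidative phosphorylation difference from Huh7 turn above 0.

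Short genes stood higher than longer genes, with rho of -0.272 and -0.318 in Hep3B, -0.303 and -0.439 in Huh7, and 0.00500 and 0.0777 in SNU449 (not tested). This could reflect elongation lost with distance, the stability of transcripts, or a technical tie to length. Thinning the controls to the treated depth moved rho in the Hep3B and Huh7 libraries by at most -0.00221, which argues against depth. Given exonic length the lowest kept share of rho was 52.1% (bootstrap 48.6 to 55.7), which leaves it open, and given GC content 85.7%, which argues against GC.

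Noncoding genes made up 56.9% of the genes higher at 500 nM, which may reflect new transcription, read-through from neighbours or genomic DNA. Olfactory receptor genes, silent in liver, gained 0.249% of what the noncoding genes gained, which argues against genomic DNA. Noncoding genes overlapping no protein-coding gene still stood at 0.28 at the lowest, and the lowest difference from matched coding genes was 0.271, both of which leave the question open.

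Among 10 groupings of the 6 libraries of each comparison, 3 against 3, most of which do not part every line, the real labels gave 646 genes at 500 nM (highest other 438), 188 at 250 nM (highest other 110) and 0 for 500 against 250 nM (highest other 1). The highest other gene count for each dose against control came from exchanging only the SNU449 control with its treated library. For each dose against control 1 of 10 groupings gave as many calls, and 10 are too few to judge. For 500 against 250 nM the real value was 0, so all 10 groupings had to give as many, and nothing follows from it. For lists the real values were 13 (highest other 11) at 500 nM and 6 (highest other 11) at 250 nM. For either dose the real labels gave 801 and the highest other 5582, a grouping that does not part every line, and 3 of 81 groupings gave as many as the real one. For the line difference, where controls were exchanged within lines, the real value was 177, the highest other 390, and 3 of 27 gave as many. Besides the real one, these exchanged only the SNU449 control with a near-identical treated library, so they kept most of the line difference. Groupings that exchanged a Hep3B or Huh7 control gave 0 genes. The share of 3 of 27 therefore cannot judge chance, which was not excluded.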

How the results depend on the processing

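Every alternative ran, and where a result moved the cause was not tested unless stated. Under total-count scaling the balance of calls at 500 nM turned to 709 higher and 1997 lower, and the list and length medians named beside their results turned sign. There is 1 library per line and dose, depth falls with dose in Hep3B and Huh7, and low totals limit the detection of small changes in weakly expressed genes. DESeq2 size factors in edgeR gave 102 genes at 250 nM and 1 for the line difference. Total-count scaling gave 2706 genes at 500 nM, 367 at 250 nM, 3295 for either dose, 4774 within Huh7 and 69 for the line difference. With no filter on low counts the numbers were 2906, 1344, 3077 and 1060 in the order 500 nM, 250 nM, either dose and line difference, and 7 for 500 against 250 nM. The stricter filter gave 74, 26, 63 and 59 in that order and 1551 within Hep3B. DESeq2 gave 1556 at 500 nM, 1601 for either dose and 769 for the line difference, and limma-voom 1083, 1465 and 387.

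Leaving out 1 line at a time gave 4 to 6324 genes at 500 nM, 0 to 3910 at 250 nM, 0 to 5 for 500 against 250 nM, 3 to 6290 for either dose, 0 to 1183 for the line difference and 2126 to 5170 within Hep3B. With no block for cell line 0 genes passed at 500 nM, 0 at 250 nM and 0 for either dose. On the 6 libraries of each comparison alone the numbers were 76 at 500 nM, 1 at 250 nM and 44 for 500 against 250 nM. Without the Huh7 500 nM library they were 30, 92, 131 for either dose, 842 for the line difference and 5385 within Hep3B. Fits on the libraries of a line alone called 1094 genes in Huh7 and 186 in SNU449. Camera with an estimated correlation called 0 lists at 500 nM and 0 at 250 nM, and fry 0 and 0. A prior count of 0.5 gave 63 genes at least 4-fold at both doses in SNU449, and a prior count of 5 gave 0.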

Other observations

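The fit on SNU449 alone was chosen only after its 0 calls were seen. It called 186 genes, 60 higher and 126 lower, but it has 1 control library, and its spread comes from 2 treated libraries at different doses. Beyond counting noise, control and 250 nM differed (chi-square per degree of freedom 3.27) no more than 250 and 500 nM did (3.57). Control and 500 nM gave 7.89, so the widest gap lies between the ends of the dose range. With 1 library per dose this cannot be told from other differences between libraries, and the calls alone do not show an effect of treatment. As values, the log2 ratios at 250 and 500 nM were -0.81 and -0.99 for the collagenase MMP1, -0.48 and -0.82 for the Wnt inhibitor DKK1, 0.45 and 0.90 for the cystine transporter SLC7A11, and 0.31 and 0.44 for CDK12.

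The lower level of homologous recombination genes may follow from their length, from fewer cells in S phase, or from the inhibited kinases. Among random lists matched on length and expression it lay at percentile 5.38 and 8.21 in Hep3B and at 1.24 and 0.77 in Huh7, at 250 and 500 nM. Both Huh7 libraries lie in the low tail of what length and expression give, and the Hep3B libraries lie less far out, which leaves length open. These possibilities can overlap, and the data do not tell them apart.

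The rise of immediate early genes could come from stress signalling, release of paused polymerase, or their short length. In each treated Hep3B and Huh7 library their median lay at percentile 100 of 10000 random lists matched on length. Homologous recombination genes lay at 5.38 and 8.21 in Hep3B and at 1.24 and 0.77 in Huh7, at 250 and 500 nM. The position of the immediate early genes argues against length as the whole cause. Nascent RNA at early times was not measured, and the data do not tell the others apart.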
